A study of Mus musculus with 23 samples.

How the data were processed

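Cells of the mouse medial ganglionic eminence (MGE) were measured by droplet-based single-cell RNA-seq of transcript 3′ ends. Both MGEs of 1 embryo were dissociated with accutase or papain and loaded as 1 library at a viability above 90%, per the labels' protocols. The authors deposited, for each of 23 libraries, a matrix of UMI counts per gene and barcode; a UMI is a molecular tag that counts each captured transcript once. These whole-number counts carry no normalization, and 32285 genes were listed in every matrix. Reads were made with bcl2fastq 2.20.0.422 and counted with Cell Ranger 7.0.0 on mouse build mm10, and Seurat 4.0.4 is also named, per the submitters' processing notes. The labels state no strand setting, cell filter or cell annotation, so the deposited barcodes were taken as they stood and cell classes were rebuilt from the counts. Gene identifiers of the files were set against the GENCODE vM21 annotation of the same build, and 32235 of the 32285 matched. Coordinates are those of that annotation, counted from 1.

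Libraries were mapped to 6 groups and 17 embryos from their labels. Repeat runs of 1 embryo were summed, so that the embryo was the replicate: 2 embryos had 3 runs, 2 had 2 runs and 13 had 1 run. The labels name 7 batches. Replicate numbers name embryos and the labels tie no number to a litter or day across groups. No 2 embryos of a group had counts that agreed within sampling noise (chi-square over genes), so none was counted as a second copy of 1 library. Separate libraries of 1 embryo would differ too, so that embryos are distinct rests on the labels.

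Barcodes with at least 1000 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were scored with scrublet in each file, and the barcodes of highest score were removed at 0.8% per 1000 barcodes kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen from rankings per file, leaving out every gene of the lists below, mitochondrial and ribosomal genes, Xist and Y-linked genes. Clusters came from 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0). They were named "X-like" from 11 marker lists: radial glia, basal progenitor, GABAergic neuron, cortical excitatory lineage, oligodendrocyte precursor, microglia, endothelium, pericyte, erythroid, meningeal fibroblast and choroid plexus. A name needed at least 3 detected markers, and a cluster stayed unnamed where markers of another class led its top 10 genes by fold. Clusters with basal progenitor markers but neuronal genes above the mean were set aside as late precursors, a threshold set after the clusters were seen; the alternative that counts them as basal progenitors was added then. A class entered a fit where an embryo had at least 20 of its cells. A first clustering, without fixed thread and hash settings, did not repeat exactly and was replaced after all its results had been seen. The 2 agreed only in part and some calls and counts differed. The added alternatives and tests of explanations were partly settled on the first.

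Depth ran from 34.7 to 100.3 M UMIs (M, 1e6) per library and from 2.19 to 79.1 M UMIs per embryo in radial glia; the median standard error of a log2 fold change in that class was 0.20 for the TEAD and 0.22 for the YAP/TAZ comparison. Raw UMI counts were summed per embryo and class and tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr) in R 4.3.3. At E14.5, 12 embryos of 4 genotypes shared 1 fit per class, which gave the TEAD effect, the YAP/TAZ effect and their difference. Wild-type embryos of both ages had a fit of their own. The effect in basal progenitors minus that in radial glia was an interaction term with the embryo as a block, within each line. Along the lineage, classes were compared within the 11 embryos without Cre, with the embryo as a block, and read only for the Hippo and target lists, whose genes took no part in the clustering. Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes come from these edgeR fits. Log2 fold changes are given ± standard error, and counts per M (CPM) as mean ± SD over embryos. CPM were scaled over the embryos of a fit, except those of targeted genes in E14.5 radial glia and in the figure of these genes, which were scaled over all 17 embryos.

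Shares of the 3 classes per embryo were compared with two-sided exact permutation tests of the difference of means (scipy 1.17.1), whose smallest possible p is 0.1 for 3 against 3 and 0.1 for 2 against 3. The 9 tests (3 comparisons, 3 classes) were adjusted together, and so were the 3 tests of the difference between the lines, which were added after seeing the data, with their alternatives. Effects in the 2 lines, which have their own controls, were correlated across genes, and overlaps of called genes were set against the number expected of independent lists. Fisher's exact test, planned for these overlaps, treats genes as independent, so its p-values are not given.

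There were 17 gene lists: canonical YAP/TAZ-TEAD targets, Hippo pathway components and TEAD partners, S phase, G2/M phase, p53 targets and apoptosis, Notch pathway, MGE interneuron, lateral ganglionic eminence (LGE) and striatal, caudal ganglionic eminence (CGE), Hedgehog pathway, apical junction and polarity, extracellular matrix and integrin, early progenitor, late progenitor and gliogenic, immediate early and dissociation stress, hypoxia and glycolysis, and integrated stress response genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 17 lists of a comparison, and again with an estimated correlation and with fry.

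Genes named in the report follow a rule. They are the targeted genes Tead1, Tead2, Yap1 and Wwtr1; among called genes with a mean log2 CPM of at least 4 and no overlap between groups, the 6 with the largest change each way (4 in neurons), leaving out class markers, clone-named, haemoglobin, mitochondrial, ribosomal protein, Xist, Tsix and Y-linked genes; and up to 4 members of each list with the smallest adjusted p. Groups, tests, lists, markers, this rule and the alternatives, apart from those named as added later, were fixed before the data were examined. Some genes that the rule selects are not reported here. Histone genes and Mfap1b belong to families or pairs of near-identical copies whose reads the counting could split, so their values are uncertain. Where all libraries of a group hold 0 counts, the fold is given against a floor of 3 counts over the group.

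Each fit was tested on simulated data drawn from the real means and library sizes, with known changes. In radial glia, the TEAD comparison recovered 22.4% of 1.5-fold, 61.2% of 2-fold and 96.9% of 4-fold changes, with 12 false calls among 14124 unchanged genes. The YAP/TAZ comparison recovered 19.4%, 62.7% and 87.7% in radial glia, 18.2%, 68.7% and 92.2% in basal progenitors, and 9.23%, 47.8% and 92.3% in neurons. In basal progenitors the TEAD comparison recovered 18.75%, 62.7% and 97.0%, and in neurons 12.1%, 54.55% and 90.6%. The difference between the lines recovered 3.03%, 20% and 80% in radial glia, with 7 false calls among 14128 unchanged genes.

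Alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0, fits of only the 2 groups compared, the replicate number as a block, batch as a term (TEAD line only), leaving out each embryo in turn, cells with at least 2000 genes and at most 5% mitochondrial UMIs, doublets kept, classes from a per-cell marker score, clustering centred within each library, run 1 only, sums thinned to equal depth, shares of all cells kept, and correlations over genes with a mean log2 CPM of at least 4. A fit without the radial glia cluster richest in TEAD knockout cells, and classes from clustering with another seed, were added after seeing the data.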

Results

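Dissociated cells of the mouse MGE, the ventral forebrain zone that generates cortical interneurons, were profiled in 23 droplet libraries from 17 embryos. The wild-type group comprised 2 embryos at E12.5 and 3 at E15.5. At E14.5 there were 4 genotypes with 3 embryos each. The TEAD line carried floxed alleles of Tead1 and Tead2, DNA-binding factors that act through partner proteins, and the YAP/TAZ line carried floxed alleles of Yap1 and of Wwtr1, the gene of the coactivator TAZ. In each line, embryos with Nes-Cre, a recombinase expressed in neural progenitors, formed the knockout group and embryos without Cre the control group. The study asked which partners TEAD factors use as radial glia give rise to basal progenitors and neurons, so that losses of TEAD and of YAP/TAZ were compared class by class.

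Depth was 72.3 and 100.3 M UMIs (M, 1e6) in the E12.5 libraries and 93.0, 70.004 and 61.4 M in the E15.5 libraries. TEAD controls held 55.5, 57.5 and 58.5 M in the 3 runs of replicate 1, 84.6 M in replicate 2 and 50.7 M in replicate 3. TEAD knockouts held 72.1, 67.5 and 74.2 M in the runs of replicate 1 and 53.2 and 80.5 M in replicates 2 and 3. YAP/TAZ controls held 35.0 and 55.9 M in the runs of replicate 1, 79.0 and 70.99 M in those of replicate 2 and 53.1 M in replicate 3, and YAP/TAZ knockouts 44.4, 34.7 and 57.7 M. YAP/TAZ knockout replicate 3 stood apart, with 19746 barcodes of median 960 UMIs, of which 5298 were kept. All YAP/TAZ knockouts were prepared in 1 batch that held no control, so batch and genotype cannot be told apart in that line. In the TEAD line, batch 2 held replicate 1 of both genotypes, while the other 2 controls were in batch 3 and the other 2 knockouts in batch 4, so batch and genotype are confounded for 2 of 3 embryos per group. Values within batch 2 rest on 1 embryo of each genotype.

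After filtering, 108741 cells remained, with 2359 to 13953 per embryo. They comprised 17080 radial glia-like cells, 28332 basal progenitor-like cells and 49466 neuron-like cells, the 3 classes compared throughout. A further 5496 cells in 1 cluster combined basal progenitor markers with neuronal genes and were kept out of the classes as late precursors, as were 7179 cells in unnamed clusters. Late precursors made up 6.55% of kept cells in TEAD knockouts and 5.22% in their controls, 6.06% and 5.15% in the YAP/TAZ line, and 0.895% at E12.5 and 5.10% at E15.5. Unnamed clusters held 3.52% and 4.91% in the TEAD line, 10.3% and 9.24% in the YAP/TAZ line, and 8.24% and 8.03% at the 2 ages. Small clusters were endothelium-like (853 cells) and erythroid-like (335). A per-cell marker score gave the same class for 85.5% of cells, and 9.42% of scored cells lay near a tie. Clustering with another seed, an alternative added after seeing the data, gave 28 clusters in place of 29 and the same class for 81.5% of the cells of the 3 classes.

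Into basal progenitors, Yap1 and Wwtr1 parted from Tead1 and Tead2. In the 11 embryos without Cre, Yap1 fell from 37.7 ± 4.34 CPM in radial glia to 7.85 ± 1.12 in basal progenitors and 1.13 ± 0.549 in neurons, and Wwtr1 from 71.003 ± 17.7 to 16.0 ± 3.29 and 1.09 ± 0.528. Tead1 instead rose from 236 ± 23.8 to 333 ± 45.4 CPM between radial glia and basal progenitors and was 100.05 ± 15.4 in neurons, and Tead2 went from 119 ± 32.7 to 173 ± 44.5 and 26.1 ± 7.48. Insm1, a zinc-finger repressor of basal progenitors, peaked at 289.6 ± 167 CPM in that class, against 99.6 ± 57.6 in radial glia and 32.0 ± 14.4 in neurons. Vgll4, a TEAD-binding antagonist of YAP, stood at 77.6 ± 12.2, 102 ± 14.6 and 79.0 ± 16.8 CPM in the 3 classes.

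From radial glia to basal progenitors, the log2 fold change was −2.26 ± 0.11 for Yap1 (adjusted p = 4.2e-15), −2.14 ± 0.12 for Wwtr1 (6.4e-14), 0.49 ± 0.05 for Tead1 (8.4e-09), 0.54 ± 0.06 for Tead2 (4.1e-09) and 1.53 ± 0.06 for Insm1 (1.7e-16), by edgeR with the embryo as a block. Of 27 measured Hippo components and TEAD partners, 13 rose and 10 fell at this step, and 4 rose and 20 fell from basal progenitors to neurons. Of 21 measured canonical YAP/TAZ-TEAD targets, 3 rose and 15 fell at the first step, and 10 rose and 9 fell at the second, so the targets did not follow Yap1 and Wwtr1 as a list into neurons. Ccn1, a secreted matricellular protein, went from 56.8 ± 27.7 to 4.07 ± 2.81 CPM, and Ajuba, a LIM-domain adaptor that binds LATS kinases, from 16.7 ± 3.94 to 2.48 ± 0.631. Rbms3 went the other way, with a log2 fold change of 1.53. Tead3 was low and fell (7.56, 4.99 and 1.77 CPM), and Tead4, Vgll1 and Vgll2 held 57, 4 and 50 counts in all and were not tested. These genes lie at 9:7931999–8004596 (Yap1, ENSMUSG00000053110), 3:57455649–57575910 (Wwtr1, ENSMUSG00000027803), 7:112679318–112906807 (Tead1, ENSMUSG00000055320), 7:45215753–45233644 (Tead2, ENSMUSG00000030796) and 2:146221921–146225020 (Insm1, ENSMUSG00000068154) in mm10.

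**Figure D1:**
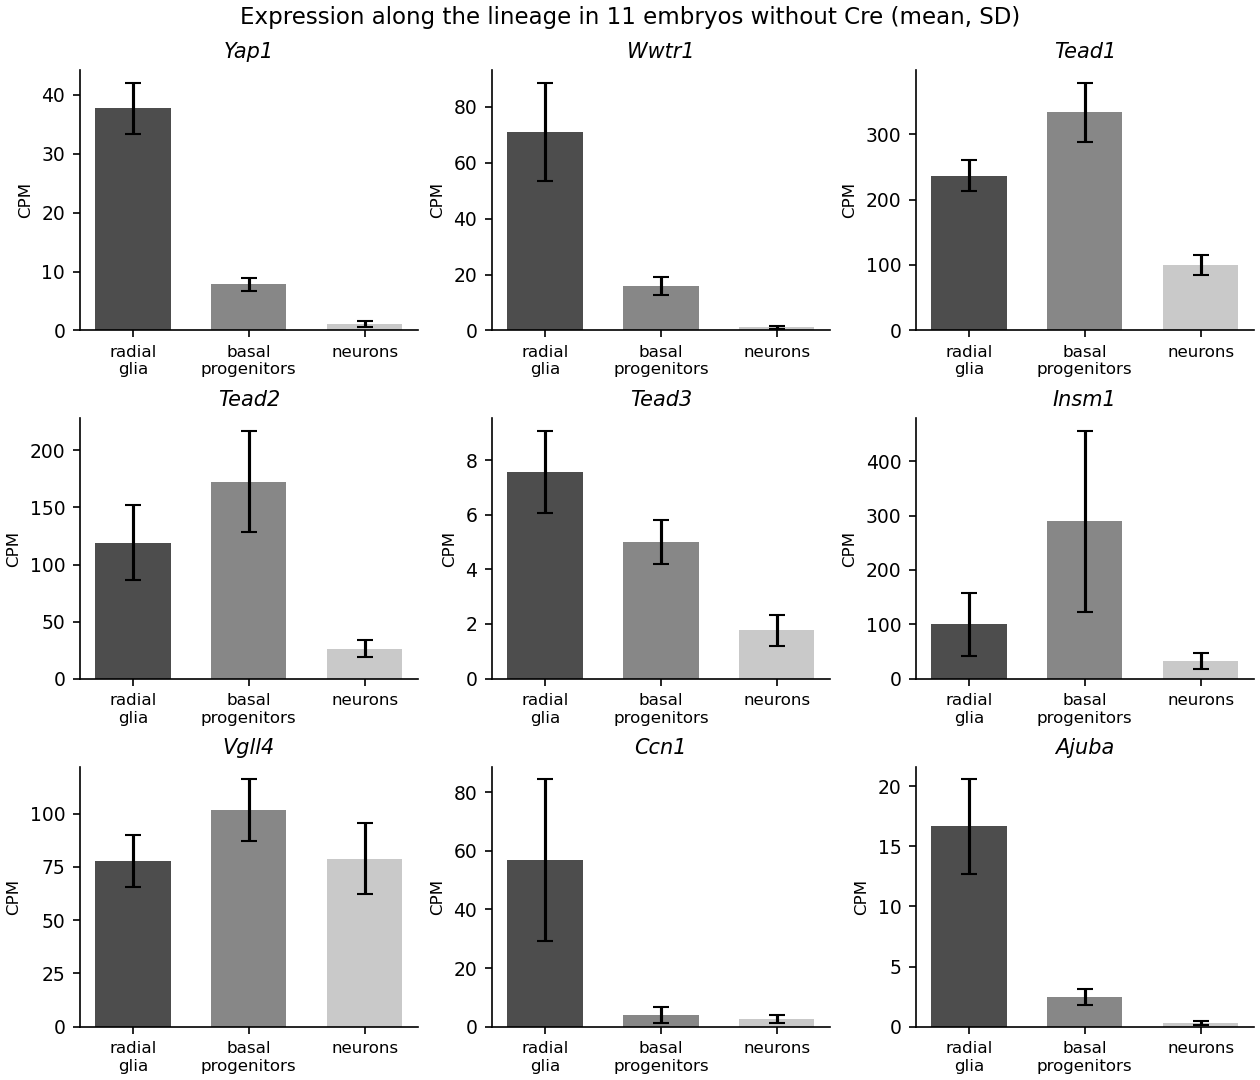
Counts per M (bars, mean; whiskers, SD over 11 embryos without Cre; vertical axes start at 0) of Hippo components, TEAD partners and target genes in radial glia-like, basal progenitor-like and neuron-like cells. Yap1 and Wwtr1 drop from 37.7 and 71.003 CPM in radial glia to 7.85 and 16.0 in basal progenitors, whereas Tead1 and Tead2 are higher in basal progenitors than in radial glia.

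The share of radial glia moved in opposite directions in the 2 lines. Radial glia made up 13.5% ± 3.38 of the 3 classes in TEAD controls and 28.5% ± 7.17 in TEAD knockouts (SD, n = 3 each), without overlap, and 16.6% against 36.5% within batch 2. In the YAP/TAZ line they made up 12.1% ± 1.15 in controls and 6.755% ± 1.06 in knockouts. Neurons went from 46.7% ± 2.33 to 39.6% ± 6.66 in the TEAD line and from 55.9% ± 3.12 to 68.1% ± 3.78 in the YAP/TAZ line. Basal progenitors went from 39.8% ± 4.53 to 31.8% ± 5.15 and from 32.0% ± 1.98 to 25.2% ± 3.12.

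Two-sided exact permutation tests gave p = 0.1 for radial glia in each line, the smallest p that 3 against 3 allows, and adjusted p = 0.129 over 9 tests. In the YAP/TAZ line p was also 0.1 for basal progenitors and for neurons, and in the TEAD line 0.2 and 0.3. As a share of all kept cells, the YAP/TAZ neuron difference of 12.2 points was 9.04, with overlap and an exact p of 0.4. The difference between the lines, tested over 400 arrangements of genotypes within lines, was 20.4 percentage points for radial glia (exact p = 0.005, adjusted p = 0.015), −19.2 for neurons (0.015 and 0.0225) and −1.20 for basal progenitors (0.85 and 0.85), a test added after seeing the data. For radial glia it was 13.4 points with clustering from another seed and 13.5 without the radial glia cluster richest in TEAD knockout cells, with an adjusted p of 0.015 in both. For neurons it did not pass with that seed, doublets kept, clustering centred within libraries or shares of all kept cells (adjusted p = 0.12, 0.142, 0.0975 and 0.0975). For basal progenitors it turned to 0.407, 0.835 and 0.515 points without TEAD control replicate 2, TEAD knockout replicate 1 or YAP/TAZ knockout replicate 3. The TEAD radial glia difference of 15.1 points was 8.93 with that seed and 9.92 without that radial glia cluster, both added after seeing the data, and the groups overlapped in neither. Without that cluster the YAP/TAZ difference of −5.34 points was −3.55. The TEAD neuron difference of −7.04 points was −1.01 with that seed, −1.06 with doublets kept, −4.17 without that cluster, −13.9 with classes from the marker score (without overlap, exact p = 0.1) and −10.9 without knockout replicate 3. With classes from the marker score, the difference in basal progenitors turned from −8.02 to 2.75 points in the TEAD line and went from −6.81 to −4.42 in the YAP/TAZ line, and the YAP/TAZ difference in radial glia was −6.35 with an exact p of 0.2.

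In wild-type embryos between E12.5 and E15.5, radial glia dropped from 39.2% ± 1.37 (n = 2) to 6.56% ± 0.958 (n = 3), and neurons increased from 45.6% ± 2.54 to 63.3% ± 3.26, without overlap (exact p = 0.1 each, the smallest that 2 against 3 allows). Basal progenitors went from 15.1% ± 1.17 to 30.1% ± 2.397 (exact p = 0.1), but differed by −0.225 points with classes from the marker score. With clustering centred within libraries the differences in radial glia, neurons and basal progenitors, −32.7, 17.6 and 15.0 points, were −52.0, 28.2 and 23.8. With classes from the marker score the radial glia difference was −20.1 (30.9% to 10.8%).

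**Figure D2:**
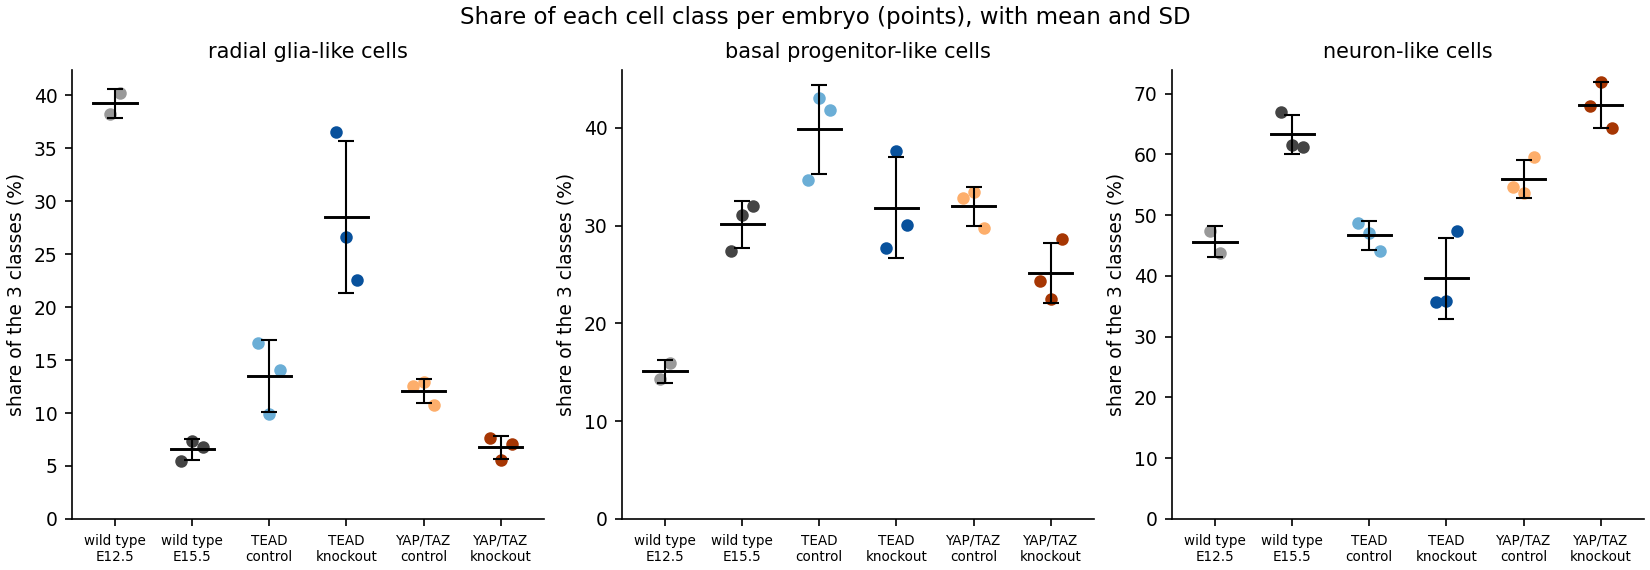
Share of radial glia-like, basal progenitor-like and neuron-like cells (percent of the 3 classes; points, embryos; lines, group mean and SD) in 6 groups. TEAD knockouts hold 22.6% to 36.5% radial glia against 9.87% to 16.6% in their controls, and YAP/TAZ knockouts lie below their controls.

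In the TEAD knockout, the targeted gene Tead2 fell in every class: in radial glia it was 71.6, 98.9 and 94.5 CPM in the controls and 44.2, 47.4 and 45.7 in the knockouts, a log2 fold change of −0.92 ± 0.13 (edgeR adjusted p = 0.0013), with −1.22 ± 0.13 in basal progenitors (0.00014) and −3.09 ± 0.21 in neurons (5.6e-05). Tead1 rose: it was 288, 228 and 211 CPM in control radial glia and 776, 449 and 444 in knockouts (1.21 ± 0.19, adjusted p = 0.0022), and rose by 1.06 ± 0.21 in basal progenitors (0.00905). The labels do not give the deleted exons, and a tag at the 3′ end outside the deleted part checks nothing, so the Tead1 counts say nothing for or against its deletion. Yap1 in radial glia was 39.8 CPM in controls and 54.8 in knockouts, and Wwtr1 80.6 and 62.0, neither past the threshold (adjusted p = 0.0779 and 0.104). Yap1 passed there without TEAD control replicate 1 (0.67, adjusted p = 0.00487) and with run 1 of each embryo (0.52, 0.0409), and Tead1 did not pass in basal progenitors without control replicate 3 (0.0502).

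**Figure D3:**
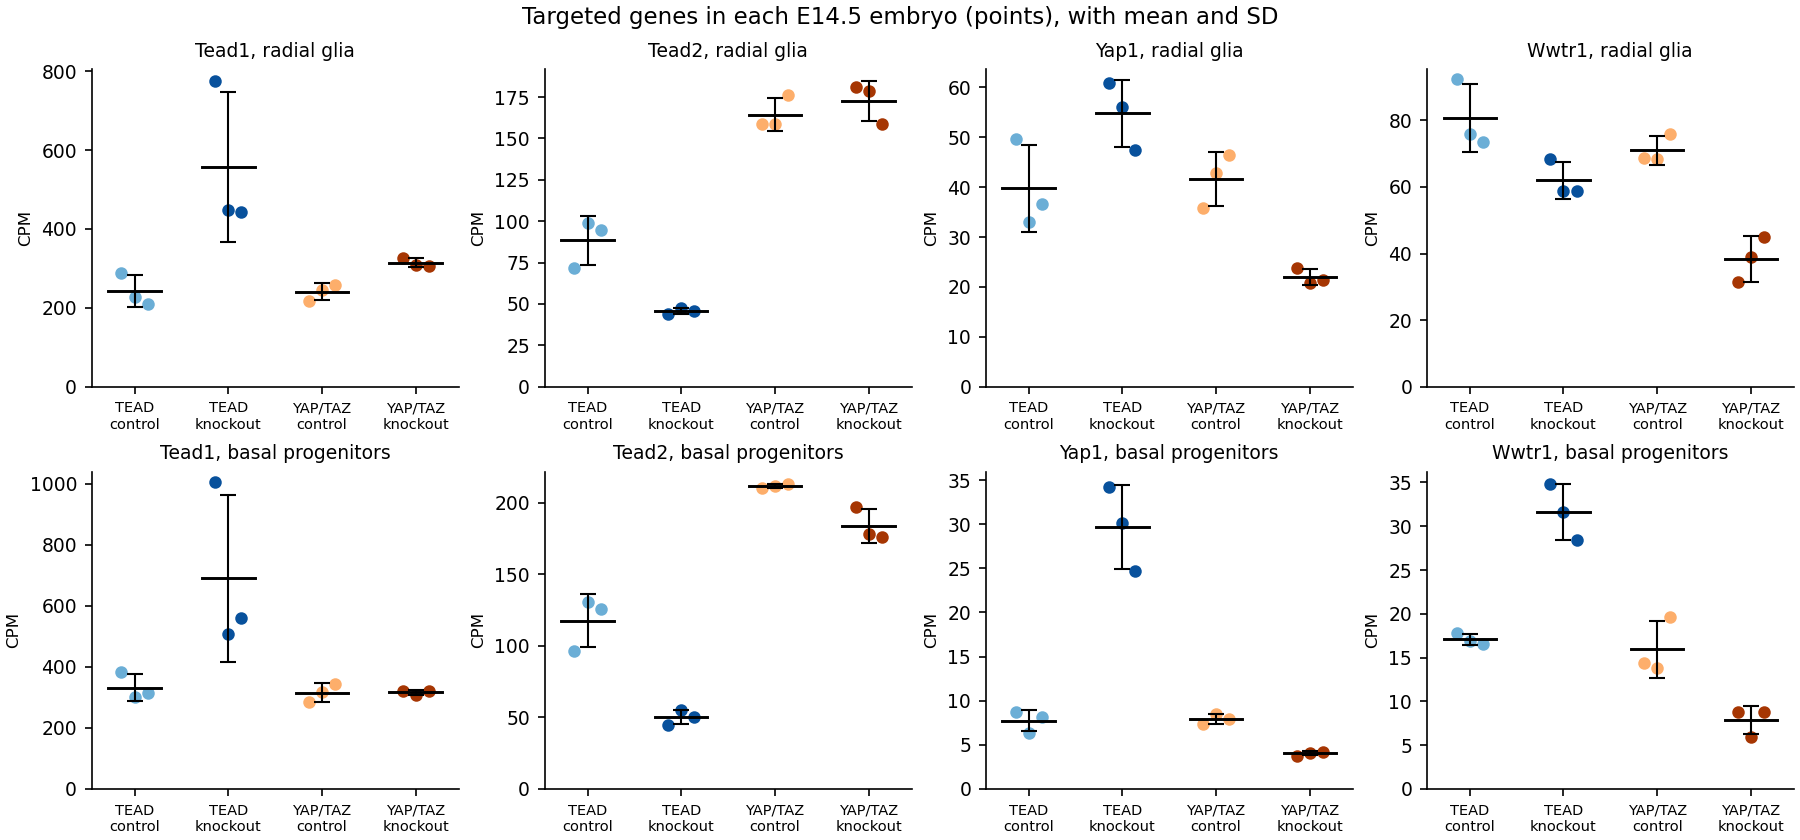
Counts per M of Tead1, Tead2, Yap1 and Wwtr1 in radial glia-like (top) and basal progenitor-like cells (bottom) of each E14.5 embryo (points, embryos; lines, mean and SD of 3). Tead2 is lower and Tead1 higher in TEAD knockouts, Yap1 and Wwtr1 are lower in YAP/TAZ knockouts, and Yap1 in basal progenitors is 29.7 CPM in TEAD knockouts against 7.72 in their controls, scaled over all 17 embryos, which differs from the scaling of the fits.

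In TEAD knockout radial glia, Pcp4, a calmodulin-binding protein, went from 86.2 ± 41.1 to 2.32 ± 1.29 CPM (log2 fold change −5.41 ± 0.50, adjusted p = 5.6e-05), and Sparc, a collagen-binding matrix protein, from 246 ± 33.9 to 9.998 ± 1.44 (−4.61 ± 0.34, 6.2e-06). Anxa5, a phospholipid-binding annexin (−3.62 ± 0.16), Aldh1l1, a folate enzyme of astroglia (−3.54 ± 0.34), and Clu, the chaperone clusterin (−3.47 ± 0.32), fell as well. The immediate early gene Fos also fell (−4.31 ± 0.80, adjusted p = 0.0051), but had −0.77 within batch 2 and −0.80 with batch as a term (adjusted p = 0.414). Among genes that rose were Pcsk5, a proprotein convertase (3.02 ± 0.37, from 9.02 to 74.5 CPM), Helt, a bHLH repressor of GABAergic progenitors (2.45 ± 0.32), and Luzp2 (2.49 ± 0.24, from 44.8 to 252 CPM). The histone genes Hist1h4n, Hist1h2br and Hist1h2ad had values of 2.60, 2.61 and 2.27, against 0.92, 0.37 and 0.09 within batch 2. With batch as a term Hist1h2br and Hist1h2ad lost the call (adjusted p = 0.465 and 0.945), as did Hist1h2ad without control replicate 3 (0.0516) and Hist1h4n and Hist1h2ad without the cluster richest in TEAD knockout cells (0.0698 and 0.129). Pcp4 lies at 16:96467606–96525793 and Sparc at 11:55394500–55423183.

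In all, 1450 of 14600 genes were called in radial glia, 675 up and 775 down, and 735 of them changed more than 2-fold. Of these, 1410 did not overlap between groups, as did 27.4% of all genes against 10% by chance, and 1438 kept their sign within batch 2. The count was 4164 without TEAD control replicate 1, whose radial glia held a median of 25539 UMIs against 19124.5 and 16107 in the other two controls. It was 796 and 693 without control replicates 2 and 3, 747 and 722 without knockout replicates 2 and 3, and 872 with classes from the marker score.

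Canonical YAP/TAZ-TEAD targets fell in TEAD knockout radial glia, 7 of 21 down and none up (8 down adjusted over the list alone; camera adjusted p = 0.0326, and adjusted p = 0.429 with an estimated correlation). Ccn1 went from 93.8 ± 26.8 to 26.5 ± 1.53 CPM (−1.82 ± 0.26, adjusted p = 0.0012) and Ajuba from 22.4 to 10.1 (−1.15 ± 0.15, 0.00077), and Ccn2, at 4.48 ± 1.01 CPM in controls and 0 counts in all knockouts, was at least 166.8-fold lower. The median log2 fold change of the list was −0.23, which Ccn2 at its bound does not move. Hippo components went both ways, with 4 up and 2 down of 27 (6 and 4 adjusted over the list alone; camera adjusted p = 0.113), among them the protocadherin gene Fat4 up (0.88).

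MGE interneuron genes rose in TEAD knockout radial glia where the classes came from clusters (6 of 24 up, none down; 8 up and 2 down adjusted over the list alone; camera adjusted p = 0.0213, and adjusted p = 0.5 with an estimated correlation). The homeobox genes Dlx1 (1.46 ± 0.28, from 125.3 to 344 CPM) and Dlx2 (1.21 ± 0.24), the GABA transporter gene Slc32a1 (1.99 ± 0.33) and Dlx6 (1.85 ± 0.35) were among them. Basal progenitor markers moved with them (2 of 10 up, median 0.54), 4 of 13 radial glia markers were down and 1 up, and 1 of 12 neuron markers was up and 3 down. Of LGE and striatal genes 4 rose and 1 fell of 13, led by Sp9 (1.64 ± 0.28, camera adjusted p = 0.149), and of 4 CGE genes none was called (smallest edgeR adjusted p 0.138, for Prox1, which passed at 0.04 with no filter on low counts). These increases depended on how the classes were drawn. With classes from the marker score, Slc32a1, Dlx6, Sp9 and Prox1 turned to −0.27, −0.24, −0.39 and −0.47 in radial glia, and Dlx1 and Dlx2 had 0.13 and 0.17 (adjusted p = 0.77 and 0.723). Dlx2 lost its call also with clustering centred within libraries (0.0652).

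Immediate early and stress genes (5 of 14 down, 8 adjusted over the list alone; camera adjusted p = 2.3e-06), glycolysis and hypoxia genes (5 of 20 down; 0.00054) and integrated stress response genes (4 of 14; 0.0015) fell, with an adjusted p of 0.429 each with an estimated correlation. Among them were Jun (−1.998 ± 0.24), Tpi1, a glycolytic isomerase (−0.92), and the serine synthesis enzyme gene Phgdh (−0.79; adjusted p = 0.0662 with batch as a term). Hedgehog genes fell (5 of 11 down; 0.0412, and adjusted p = 0.5 with an estimated correlation), including Hhip (−1.54 ± 0.28) and Ptch1 (−0.82 ± 0.14), which encode a Hedgehog-binding protein and the receptor. Ptch1 had an adjusted p of 0.0539 with classes from the marker score. The cell cycle lists did not pass. Of 52 G2/M genes 1 was down (camera adjusted p = 0.278), Tubb4b at −0.99, which lost its call with batch as a term (0.134) and without control replicate 3 (0.0876), knockout replicate 1 (0.0551) or knockout replicate 3 (0.0548). None of 42 S phase genes was called. The smallest adjusted p was 0.0749, for Ubr7 (0.46), which passed without control replicate 1 (0.0142) or knockout replicate 1 (0.0382) and had −0.07 with batch as a term. Early progenitor genes had 2 of 10 down, with Hmga2, a chromatin protein of young progenitors, at −2.51 ± 0.17; the list's median was 0.24, its mean −0.23 and its test downward (0.46).

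Other lists that did not pass in radial glia were Notch (3 up, 1 down of 14), p53 and apoptosis (2 and 1 of 26), apical junction (1 and 2 of 19), matrix and integrin (3 and 2 of 21) and late progenitor genes (4 and 3 of 20, with Nfib at 1.11 and Fgfr3 at −1.33). Among markers of other cells, 1 of 2 microglia markers was up and 1 of 2 meningeal markers was down, while none of 5 oligodendrocyte precursor, 3 endothelium, 2 pericyte, 6 erythroid (median −1.63) and 1 choroid plexus markers was called.

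In TEAD knockout basal progenitors, Yap1 rose from 7.53 ± 1.18 to 29.1 ± 4.32 CPM (log2 fold change 1.95 ± 0.15, adjusted p = 1.55e-05; 1.97 within batch 2) and Wwtr1 from 16.7 ± 0.544 to 31.0 ± 2.74 (0.90 ± 0.16, 0.0048; 0.96 within batch 2). Gad1, which makes GABA, went from 99.5 ± 9.73 to 32.9 ± 9.25 CPM (−1.59 ± 0.17, 0.00016), Svop, a synaptic vesicle protein, from 56.7 to 17.4 (−1.69 ± 0.21), and Grin2b, a glutamate receptor subunit, from 25.1 to 6.74 (−1.89 ± 0.25). Rundc3a (−1.54 ± 0.17), Erbb4, the neuregulin receptor of interneurons (−1.63 ± 0.35), and Srrm3, a neuronal splicing factor (−1.53 ± 0.14), fell as well. Rest, a repressor of neuronal genes, rose from 12.535 ± 1.83 to 51.7 ± 4.38 CPM (2.05 ± 0.16), as did the stress-response gene Ddit4l (2.96 ± 0.18), the ubiquitin ligase gene Pdzrn3 (2.31 ± 0.28), the TGF-beta effector Smad3 (2.05 ± 0.25) and the Wnt pathway factor Tcf7l1 (1.88 ± 0.26). The histone gene Hist1h4n had 2.14, against 0.52 within batch 2, and lost the call with batch as a term (0.129) or without knockout replicate 3 (0.0542). When the marker score set the classes, Gad1 had −0.63 (adjusted p = 0.0207), whereas Erbb4 (−0.13, 0.788) lost the call. Erbb4 lost it also without knockout replicate 2 or 3 (0.0748 and 0.079) and with doublets kept (0.181). Gad1 lies at 2:70553072–70602014.

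MGE interneuron genes fell as a list: 9 of 24 were down and none up (14 down adjusted over the list alone; median −0.55, camera adjusted p = 7.3e-08, and adjusted p = 0.0108 with an estimated correlation). Lhx8, a homeobox factor of MGE neurons, went from 144 to 52.5 CPM (−1.45 ± 0.20), and Slc32a1 from 51.2 to 28.5 (−0.85 ± 0.12). Neuron markers moved with them, 6 of 12 down (median −0.60), and radial glia markers the other way, 3 of 13 up (median 0.25), whereas basal progenitor markers were 1 up and 1 down of 11. Of 3 oligodendrocyte precursor markers 2 were up (median 0.77, highest 3.72), and no marker of the other cell types was called (erythroid median −1.70). This decline, too, depended on how the classes were drawn. Under marker-score classes, 6 of the 15 genes called down from the interneuron and neuron lists stayed called in basal progenitors, and their median went from −1.16 to −0.63. In radial glia it went from −0.52 to −1.09. Slc32a1 (−0.38, adjusted p = 0.109) was among those that lost the call, while Lhx8 kept it (−1.18). With batch as a term Slc32a1 had an adjusted p of 0.0565.

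Canonical YAP/TAZ-TEAD targets rose in this class: 5 of 19 were up and none down (5 adjusted over the list alone; median 0.31, camera adjusted p = 0.0084, and adjusted p = 0.0938 with an estimated correlation). They included Ajuba (0.90 ± 0.21, from 2.80 to 5.28 CPM), the angiomotin gene Amotl2 (0.75 ± 0.14), the LATS kinase gene Lats2 (0.70 ± 0.14) and Fjx1 (0.65 ± 0.16). Without control replicate 3, knockout replicate 2 or knockout replicate 3, Ajuba (adjusted p = 0.117, 0.114 and 0.0903) and Fjx1 (0.1, 0.116 and 0.105) lost their calls, as did Lats2 without control replicate 3 (0.0513). Ajuba lost it also with classes from the marker score (0.69, adjusted p = 0.0504) or batch as a term (0.197) and Amotl2 with clustering centred within libraries (0.0567), while Yap1 (1.80) and Wwtr1 (0.65) kept theirs under the marker score. The interneuron list here, the targets in YAP/TAZ knockout basal progenitors, and both lists in the difference between the lines are the 4 of 80 list calls that hold with an estimated correlation, out of 238 tests over 14 comparisons.

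Hippo components rose (5 up, 1 down of 27; camera adjusted p = 0.0027), as did Notch genes (3 up, 2 down of 13; 0.0165; adjusted p = 0.44 and 0.122 with an estimated correlation), with Notch2 at 1.15 ± 0.17. Apical junction genes (1 up of 19; 0.0165) and matrix genes (2 up, 1 down of 20; 0.0165; adjusted p = 0.478 and 0.499 with an estimated correlation) also rose. G2/M genes (13 down of 52, 31 adjusted over the list alone; 8.4e-14), S phase genes (2 down of 42; 0.0105) and immediate early genes (3 down of 16; 0.0065) fell, with an adjusted p of 0.122, 0.522 and 0.522 with an estimated correlation. Among them were Cdc25c, a mitotic phosphatase, at −0.77, the ribonucleotide reductase subunit Rrm2 at −0.75 and Dusp1, a stress phosphatase, at −0.96. With batch as a term Cdc25c had −0.41 (adjusted p = 0.115) and Rrm2 −0.47 (0.0856). LGE and striatal genes went both ways (3 up and 2 down of 14, median −0.34, mean 0.21; camera adjusted p = 0.865), with Foxp2 rising from 48.4 to 168 CPM.

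In all, 989 of 15414 genes were called in basal progenitors, 490 up and 499 down, 438 of them more than 2-fold. Of these, 964 did not overlap between groups, as did 22.5% of all genes against 10% by chance, and 981 kept their sign within batch 2. The count was 3979, 522 and 372 without TEAD control replicates 1, 2 and 3 and 473 and 397 without knockout replicates 2 and 3; it was 646 with batch as a term, 316 when only the 2 groups were fitted and 1589 by DESeq2. Cluster 13 was the largest of the class in knockouts (29.7%) and controls (26.3%), followed by cluster 9 in knockouts (23.8%, against 15.0% in controls) and cluster 12 in controls (24.7%).

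In TEAD knockout neurons 10 of 16286 genes were called, 9 up and 1 down, of which 10 kept their sign within batch 2. Simulated data gave 15 false calls in this comparison, so single calls other than Tead2 are uncertain. Apart from Tead2, they included Pde5a, a cGMP phosphodiesterase (1.80 ± 0.21, from 24.6 to 85.7 CPM, adjusted p = 0.0159), Shtn1, a regulator of axon outgrowth (1.403 ± 0.20, 0.0232), and Tfdp2, an E2F partner (0.82 ± 0.11, 0.0159). Each of these 3 lost its call without control replicate 2 (adjusted p up to 0.122), control replicate 3 (up to 0.209) or knockout replicate 2 (up to 0.0831), Shtn1 also without YAP/TAZ knockout replicate 3 (0.0552), and with batch as a term adjusted p reached 0.216. Immediate early genes fell as a list (0 of 15 called; camera adjusted p = 0.0081, and adjusted p = 0.713 with an estimated correlation), and no marker was called, with medians of −0.26 for cortical excitatory and −2.10 for erythroid markers. DESeq2 called 299 and the marker-score classes gave 312. The count was 2524 without TEAD control replicate 1, 1 without control replicate 2, control replicate 3 or knockout replicate 2, and 20 without knockout replicate 1. Clusters 18 (27.9%) and 28 (24.4%) held the most neurons in knockouts and clusters 21 (18.0%) and 18 (16.9%) in controls.

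The TEAD effect differed between basal progenitors and radial glia for 3829 of 16129 genes, 1863 of them higher and 1966 lower in basal progenitors (edgeR interaction, 6 embryos). Yap1 (1.52 ± 0.10, adjusted p = 1.2e-07) and Wwtr1 (1.29 ± 0.08, 1.7e-07) were shifted upward in basal progenitors, as were Pcp4 (3.15 ± 0.33) and Ccn1 (2.205 ± 0.18). Of 21 canonical targets 9 were shifted up and 2 down (13 and 2 adjusted over the list alone; camera adjusted p = 0.0002). MGE interneuron genes were shifted down, 20 of 24 (1.9e-11; adjusted p = 0.241 for both lists with an estimated correlation), with Slc32a1 at −2.89 ± 0.16, Dlx1 at −1.78 ± 0.08 and Dlx2 at −1.51 ± 0.06. Of 12 neuron markers 8 were shifted down and 1 up, and of 14 radial glia markers 9 up and 1 down. Of basal progenitor markers 5 of 11 were shifted down, and of meningeal markers 2 of 3 (median 1.74), of oligodendrocyte precursor markers 2 of 5 (highest 4.77) and of choroid plexus markers 1 of 2 were shifted up. Glycolysis and hypoxia genes (14 up, 1 down of 20; 2e-07) and integrated stress response genes (8 up of 14; 8.2e-05; adjusted p = 0.241 and 0.231 with an estimated correlation) were shifted up, with Ldha at 0.93 and Psat1 at 1.32. With classes from the marker score the count was 1597, and the median shift of the 15 interneuron and neuron genes called down in basal progenitors turned from −0.80 to 0.27, with 5 called up and 1 down. Dlx1 and Dlx2 then had −0.55 and −0.54 and Slc32a1 −0.15 (adjusted p = 0.5), while Yap1 and Wwtr1 kept their upward shift (1.14 and 0.79).

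In the YAP/TAZ knockout, both targeted genes fell in radial glia. Wwtr1 was 68.6, 68.5 and 76.0 CPM in controls and 31.4, 38.8 and 45.1 in knockouts (log2 fold change −0.86 ± 0.15, adjusted p = 0.0097), and Yap1 35.7, 42.9 and 46.4 against 23.8, 20.8 and 21.4 (−0.89 ± 0.18, adjusted p = 0.0251). In basal progenitors Yap1 had −0.94 ± 0.17 (0.0419) and Wwtr1 −0.97 ± 0.17 (0.0436), and in neurons −0.89 and −0.80 (0.534 and 0.616). Tags outside the deleted exons check nothing here either. Tead1 and Tead2 had 0.42 and 0.10 in radial glia (0.293 and 0.752). The calls in radial glia were lost for Yap1 without control replicate 2 (adjusted p = 0.104) or knockout replicate 1, 2 or 3 (0.0727, 0.122 and 0.0947) and with thinned sums (0.275), and for Wwtr1 without knockout replicate 1 or 2 (0.0537 and 0.0559). In basal progenitors both were lost without TEAD control replicate 3 (0.0654 and 0.0729), TEAD knockout replicate 2 (0.0726 each), YAP/TAZ control replicate 1 (0.118 each) or 2 (0.167 and 0.0917) or YAP/TAZ knockout replicate 1 (0.16 and 0.123), 2 (0.181 and 0.21) or 3 (0.152 and 0.13), with another clustering seed (0.0965 and 0.0611) and with doublets kept (0.217 and 0.128). Wwtr1 was lost there also without TEAD control replicate 2 (0.0588) or TEAD knockout replicate 3 (0.0634).

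YAP/TAZ knockout radial glia lost transcripts of several genes that also fell in TEAD knockout radial glia. Pcp4 went from 100.2 ± 28.4 to 3.58 ± 1.79 CPM (−4.83 ± 0.56, adjusted p = 0.00083), Clu from 37.1 to 2.51 (−3.85 ± 0.41), Sparc from 198 to 26.9 (−2.83 ± 0.33) and the annexin gene Anxa2 from 67.7 to 11.1 (−2.67 ± 0.28). Ccn1 went from 63.2 ± 17.6 to 8.20 ± 3.66 CPM (−2.90 ± 0.32, 0.00046). Canonical targets fell, 6 of 21 down and none up (10 down and 2 up adjusted over the list alone; median −0.76, camera adjusted p = 7.6e-06, and adjusted p = 0.0819 with an estimated correlation), including Tgfb2 (−1.85), F3, the tissue factor gene (−1.58), and Ajuba (−1.20 ± 0.19). G2/M genes rose as a list (0 of 52 called; 0.00046, and adjusted p = 0.91 with an estimated correlation), and no other list passed. Wwc2, a LATS-activating scaffold, fell by 1.64. Npy, a neuropeptide of interneurons, rose from 14.0 to 82.8 CPM (2.58 ± 0.45, 0.0111), Dlx2 from 79.4 to 209.9 (1.41 ± 0.25) and Sp9 from 23.8 to 64.2 (1.42 ± 0.29). The histone genes Hist2h2aa1, Hist1h2br, Hist1h2bg, Hist1h4k and Hist1h2ad had values from 2.19 to 2.86.

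Pcp4, Clu, Sparc, Anxa2, Ccn1, Ajuba, F3 and Hist2h2aa1 kept their calls without any single embryo, and Wwc2 lost its call without YAP/TAZ knockout replicate 2 (adjusted p = 0.0523). Tgfb2, Npy, Dlx2, Sp9 and the other histone genes lost theirs without 2 or more of them (adjusted p up to 0.148 and 0.173 without YAP/TAZ control replicates 1 and 2, up to 0.112, 0.142 and 0.0773 without knockout replicates 1, 2 and 3, and up to 0.0514 without TEAD knockout replicate 3). With doublets kept Npy and Sp9 had 0.168 and 0.307, with another clustering seed Sp9 had 0.12, and without the cluster richest in TEAD knockout cells Tgfb2, Ajuba and F3 had 0.0763, 0.0611 and 0.0809. In all, 253 of 14600 genes were called, 82 up and 171 down; all 253 lacked overlap between groups, as did 25.4% of all genes against 10% by chance. The count was 610 without TEAD control replicate 1, 99, 75 and 540 without YAP/TAZ control replicates 1, 2 and 3, 97, 68 and 106 without knockout replicates 1, 2 and 3, and 557 by DESeq2. Cluster 7 held 54.8% of control and 36.5% of knockout radial glia and cluster 11 36.1% and 35.6%. Cluster 8 (median 3529.5 UMIs, histone genes in its top 10) held 6.25% and 24.4%, whose part in the calls was not tested. Of 13 radial glia markers 1 was down, 1 of 5 oligodendrocyte precursor markers was up (median 1.39), and erythroid markers had a median of −1.49 with none called.

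Few genes were called in YAP/TAZ knockout basal progenitors, 11 up and 18 down of 15414. Sparc (−3.20 ± 0.26, adjusted p = 0.00019) and Dleu7 (−1.60 ± 0.18, from 45.4 to 14.9 CPM) fell, with the mitochondrial gene Fam210b (−1.23 ± 0.20) and the LIM-domain gene Fhl1 (−0.80 ± 0.12). Npy rose from 61.7 to 161 CPM (1.39 ± 0.22, 0.0271), and Hist2h2aa1, Hist1h2ah and Mfap1b had values of 1.75, 1.67 and 0.67. Canonical targets fell as a list without a called member (0 of 19, 2 adjusted over the list alone; median −0.33, camera adjusted p = 0.00054, and adjusted p = 0.0417 with an estimated correlation); Ajuba had −1.06 (adjusted p = 0.131). G2/M and MGE interneuron genes rose as lists (camera adjusted p = 3e-08 and 0.0075, and adjusted p = 0.425 and 0.141 with an estimated correlation). None of the marker lists had a called member. Of the called genes named here Sparc and Dleu7 kept their calls without any single embryo. The others lost theirs without at least 5 of them (adjusted p up to 0.127 and 0.12 without YAP/TAZ control replicates 1 and 2, up to 0.117, 0.181 and 0.168 without knockout replicates 1, 2 and 3, and for Mfap1b 0.0554 and 0.0726 without TEAD control replicate 3 and TEAD knockout replicate 2). The count was 114 without TEAD control replicate 1, 70 without TEAD knockout replicate 1, 5, 7 and 284 without YAP/TAZ control replicates 1, 2 and 3, and 6, 5 and 7 without knockout replicates 1, 2 and 3. It was 205 by DESeq2, 242 when only the 2 groups were fitted and 13 with another clustering seed.

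No gene was called by edgeR in YAP/TAZ knockout neurons, where 1489 of 16286 had an unadjusted p under 0.05 and DESeq2 called 112. As lists, G2/M genes fell (median −0.96, 18 of 52 down adjusted over the list alone; camera adjusted p = 6.8e-15), and so did S phase genes (1.1e-05; adjusted p = 0.279 and 0.352 with an estimated correlation). Hedgehog (0.0063), Notch (0.021) and late progenitor genes (0.021) fell too, with an adjusted p of 0.279, 0.225 and 0.225 with an estimated correlation. Top2a, a mitotic topoisomerase, was 29.7 CPM in controls and 8.29 in knockouts (−1.85 ± 0.44, adjusted p = 0.252). MGE interneuron genes (median 0.26; 0.00019) and glycolysis and hypoxia genes (median 0.43; 1.5e-05; adjusted p = 0.225 and 0.352 with an estimated correlation) rose as lists, with Maf at 1.79 (adjusted p = 0.146) and Eno1 at 0.88 (0.146). Radial glia markers had a median of −0.74 and erythroid markers of −2.36, with none called. Different clusters led, cluster 28 in knockouts (23.9%) and cluster 17 in controls (13.7%); the count was 6 without TEAD knockout replicate 1, 10 without YAP/TAZ control replicate 3 and 6 without YAP/TAZ knockout replicate 1.

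The YAP/TAZ effect differed between basal progenitors and radial glia for 143 of 15477 genes, 99 higher and 44 lower in basal progenitors. Sh3rf3, a JNK scaffold (1.61 ± 0.14, adjusted p = 0.000345), Mest, an imprinted gene (1.53 ± 0.19), Pcp4 (2.97 ± 0.46), Ccn1 (2.10 ± 0.42) and Notch2 (0.73 ± 0.15) were shifted up, and Dlx1 (−1.26 ± 0.20) and Dlx2 (−1.07 ± 0.19) down. Yap1 (−0.06, adjusted p = 0.919) and Wwtr1 (−0.05, 0.942) showed no shift past the threshold and no fixed direction. Yap1 had 0.05 without knockout replicate 1, and Wwtr1 had 0.02, 0.09 and 0.02 without control replicate 3 and knockout replicates 2 and 3 and 0.22 with another clustering seed. Of the called genes Sh3rf3 and Mest kept their calls without any single embryo. The others had adjusted p up to 0.16 and 0.149 without control replicates 1 and 2 and up to 0.177, 0.156 and 0.171 without knockout replicates 1, 2 and 3, and Ccn1 had 0.0599 with the marker score. Canonical targets did not pass (1 of 21 called; camera adjusted p = 0.0623), and S phase genes were shifted down as a list (4.9e-06, and adjusted p = 0.885 with an estimated correlation), with 1 of 14 radial glia and 1 of 12 neuron markers shifted up and 1 of 11 basal progenitor markers down. The count was 39, 41 and 613 without control replicates 1, 2 and 3 and 61, 24 and 88 without knockout replicates 1, 2 and 3.

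The 2 lines differed most in basal progenitors. There the TEAD effect exceeded the YAP/TAZ effect or fell below it for 309 of 15414 genes, 139 of them higher in the TEAD line. Yap1 (2.90 ± 0.22, adjusted p = 8.4e-05) and Wwtr1 (1.86 ± 0.24, 0.0019) differed, as did Ddit4l (3.33 ± 0.27), Rest (2.55 ± 0.23), Foxp2 (2.51 ± 0.27) and Pdzrn3 (2.44 ± 0.40), all higher with TEAD loss. Gad1 (−1.88 ± 0.24), Scrt1, a neuronal zinc-finger factor (−1.71 ± 0.15), and the synaptic gene Snap25 (−1.58 ± 0.24) were lower. Canonical targets were higher (2 of 19 called, 5 adjusted over the list alone; camera adjusted p = 4.9e-06, and adjusted p = 0.00585 with an estimated correlation), with Ajuba at 1.96 ± 0.33, which lost its call with thinned sums (0.182). MGE interneuron genes were lower (8 of 24, 14 adjusted over the list alone; 1.4e-10, and adjusted p = 0.0038 with an estimated correlation), with 4 of 12 neuron markers lower and 1 of 11 basal progenitor markers higher beside them.

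The count in basal progenitors was 2401, 181 and 149 without TEAD control replicates 1, 2 and 3, 184 and 151 without TEAD knockout replicates 2 and 3, 148 and 192 without YAP/TAZ control replicates 1 and 2, and 195, 139 and 143 without YAP/TAZ knockout replicates 1, 2 and 3. In radial glia 6 genes differed, among them Anxa5 (−1.62 ± 0.23) and the secretogranin gene Scg3 (−1.12 ± 0.17), lower with TEAD loss, and Fam126a (1.27 ± 0.18) and Zfhx4 (1.503 ± 0.23), higher. These 4 kept their direction but not their call, with adjusted p up to 0.14 and 0.159 without TEAD control replicates 2 and 3, 0.0863, 0.138 and 0.143 without TEAD knockout replicates 1, 2 and 3, 0.157 and 0.0954 without YAP/TAZ control replicates 2 and 3, 0.132, 0.164 and 0.103 without YAP/TAZ knockout replicates 1, 2 and 3, and 0.2 with another clustering seed. DESeq2 called 83. The count by edgeR was 1814 without TEAD control replicate 1, 1 without TEAD control replicate 2 or 3, TEAD knockout replicate 2 or 3 or YAP/TAZ control replicate 2, and 3, 2 and 3 without YAP/TAZ knockout replicates 1, 2 and 3. In neurons 1 gene differed, Tead2 (−2.74 ± 0.27, adjusted p = 0.0047; 0.0721 with doublets kept), and 727 did without TEAD control replicate 1. Since all YAP/TAZ knockouts share a batch, these differences include any effect of it.

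Across genes, the effects of the 2 losses in radial glia had a Pearson correlation of 0.501 and a Spearman correlation of 0.355, against 0.204 and 0.109 in basal progenitors and 0.309 and 0.279 in neurons. Over genes with a mean log2 CPM of at least 4, they were 0.459 and 0.220 in radial glia, 0.112 and −0.0273 in basal progenitors and 0.400 and 0.254 in neurons, so the Spearman correlation turned in basal progenitors and was higher in neurons than in radial glia. Genes are not independent replicates, so neither these relations nor the overlaps carry a p-value. In radial glia 117 genes fell in both lines, where 9.08 are expected of independent lists, and 50 rose in both (3.79 expected), while 3 rose with TEAD loss and fell with YAP/TAZ loss and 0 did the reverse (7.91 and 4.35 expected).

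**Figure D4:**
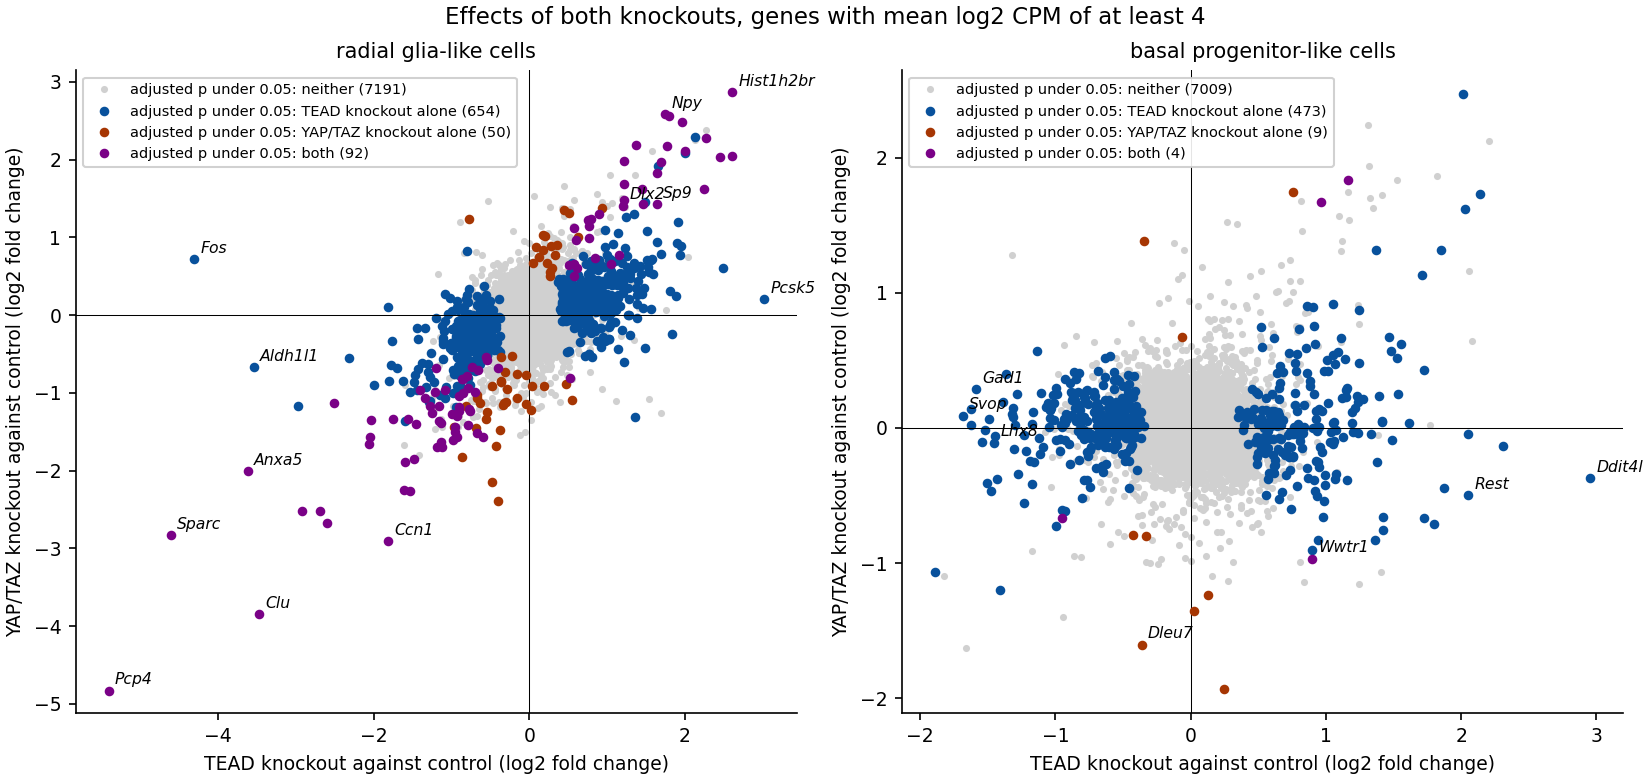
Log2 fold change with YAP/TAZ loss against that with TEAD loss in radial glia-like (left) and basal progenitor-like cells (right), 1 point per gene with a mean log2 CPM of at least 4, coloured by the comparison that called it. In radial glia 92 such genes are called in both lines, 654 with TEAD loss alone and 50 with YAP/TAZ loss alone, against 4, 473 and 9 in basal progenitors.

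**Figure D5:**
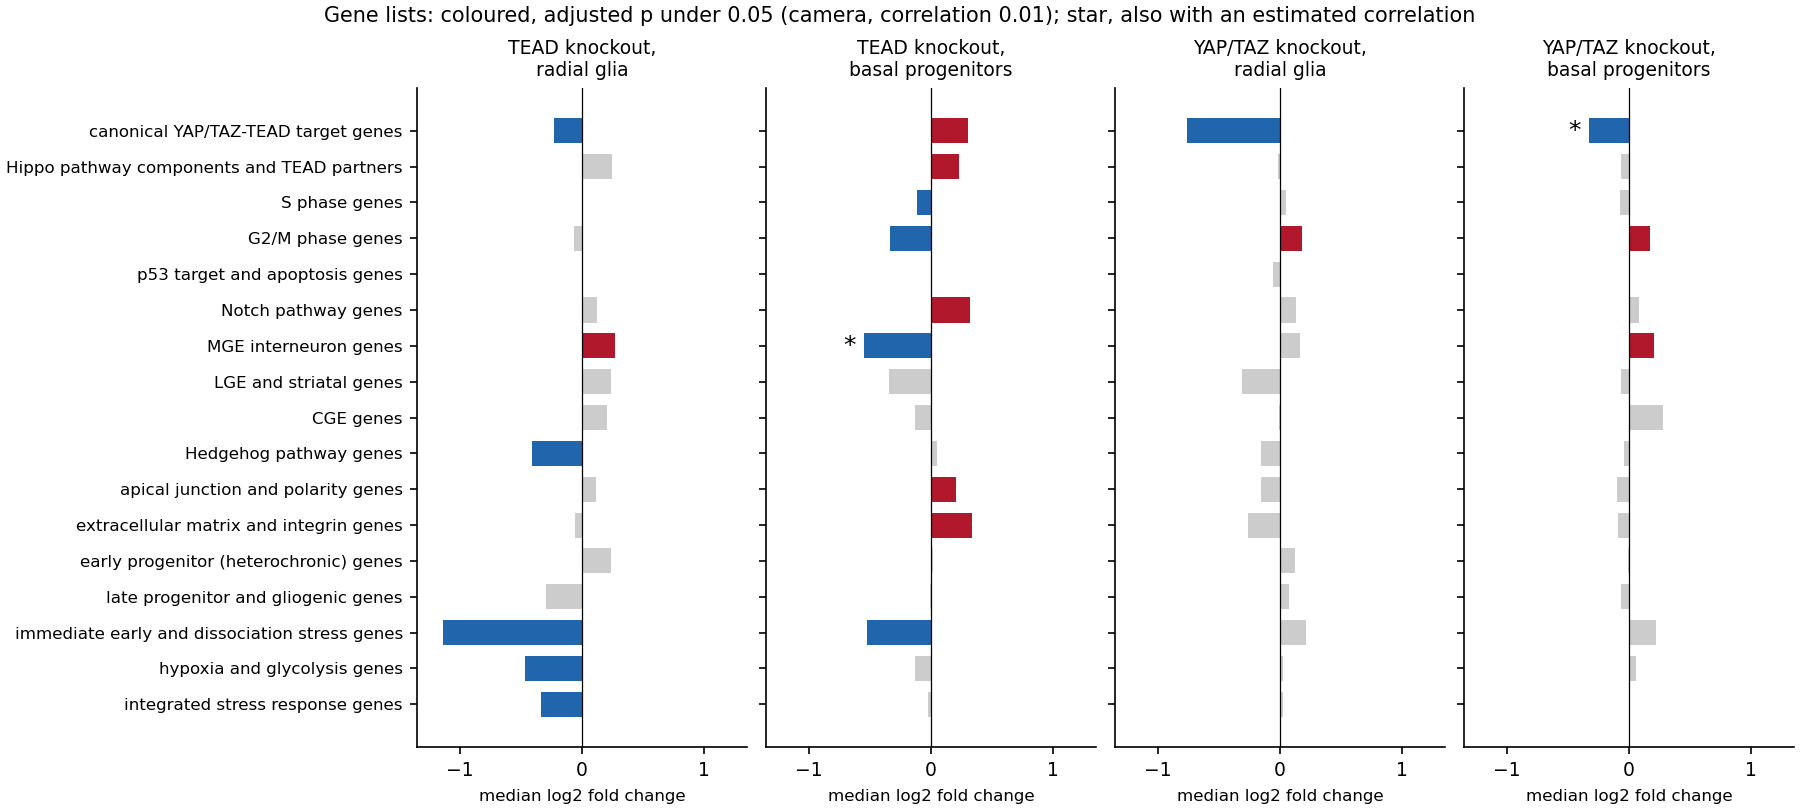
Median log2 fold change of 17 gene lists (bars) with TEAD or YAP/TAZ loss in radial glia-like and basal progenitor-like cells; coloured bars passed camera at an adjusted p under 0.05, and stars mark those that also pass with an estimated correlation. Stars fall on the MGE interneuron genes of TEAD knockout basal progenitors (median −0.55) and the targets of YAP/TAZ knockout basal progenitors (−0.33).

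In wild-type radial glia from E12.5 to E15.5, Crabp2, a retinoic acid carrier, went from 162 to 6.32 CPM (log2 fold change −4.68 ± 0.13, adjusted p = 9.15e-10), the morphogen gene Shh from 29.9 to 0.624 (−5.75 ± 0.34) and the cell-cycle inhibitor gene Cdkn1c from 359.9 to 42.7 (−3.06 ± 0.14). Egfr, the EGF receptor (8.21 ± 0.42, from 0.182 to 57.3 CPM), Aldh1l1 (7.85 ± 0.25) and Ndrg2 (5.04 ± 0.14), the latter both astroglial genes, rose. Late progenitor genes rose (15 of 19 up, 1 down; camera adjusted p = 1.5e-10), and early progenitor genes fell (10 of 11; 2.8e-09; adjusted p = 0.133 for both with an estimated correlation), with Nfix at 3.29 and Hmga2 at −2.74. S phase (38 of 42; 2.5e-15), G2/M (16 down, 3 up of 52; 0.0162) and CGE genes (4 of 4; 0.00068) fell, with an adjusted p of 0.377, 0.489 and 0.371 with an estimated correlation. Matrix genes rose (12 up, 4 down of 20; 0.0308), and so did canonical targets (8 up, 2 down of 18; 0.0421; adjusted p = 0.519 for both with an estimated correlation). Markers of pericytes (2 of 2, median 2.51), meninges (2 of 2, median 1.22) and endothelium (1 of 2) were up beside them. Wwtr1 rose from 45.9 to 97.7 CPM (1.09 ± 0.11), whereas Yap1 (−0.03, adjusted p = 0.821) and Tead1 (0.15, 0.221) did not pass and Tead2 fell by 0.45. Under marker-score classes Yap1 had −0.72 (adjusted p = 0.00011) and Tead1 0.41 (0.0037). Yap1 had 0.01 without E15.5 replicate 2 and 0.15 with thinned sums. In all 5722 of 13499 genes were called, 3020 up and 2702 down. Clusters 5 (52.3%) and 20 (39.3%) held most radial glia at E12.5 and clusters 7 (53.5%) and 11 (36.3%) at E15.5, and of 10 basal progenitor markers 8 were down and 1 up, of 13 radial glia markers 6 up and 2 down, of 12 neuron markers 3 up and 4 down and of 5 oligodendrocyte precursor markers 2 up and 3 down.

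In basal progenitors 5764 of 15173 genes were called with age, 3018 up and 2746 down, led by Luzp2 (6.16 ± 0.13, from 1.58 to 117 CPM) and Nfix (4.21 ± 0.11) up and Crabp2 (−3.89 ± 0.15) and Dlk1, a Notch ligand-like gene (−3.27 ± 0.11), down. Insm1 rose by 0.91 ± 0.13. S phase genes, unlike in radial glia, rose (38 of 42 up; camera adjusted p = 8.7e-15), as did G2/M genes (39 of 52 up; 8.7e-15; adjusted p = 0.284 and 0.316 with an estimated correlation). Integrated stress response genes (10 of 16 up; 0.00018) and late progenitor genes (9 up, 3 down of 19; 0.025; adjusted p = 0.623 for both with an estimated correlation) rose as well. Early progenitor genes (9 of 12; 7.6e-07) and glycolysis and hypoxia genes (13 down, 2 up of 20; 1.9e-05; adjusted p = 0.284 and 0.4223 with an estimated correlation) fell. Of 11 basal progenitor markers 3 were up and 6 down, and of 13 radial glia markers 5 up and 5 down. In neurons 5328 of 16538 genes were called, 2849 up and 2479 down, with Nfix (6.56 ± 0.32) and the protocadherin gene Dchs2 (6.24 ± 0.20) up and Crabp2 (−4.76 ± 0.19) and Robo3, an axon guidance receptor (−4.49 ± 0.13), down; LGE and striatal genes rose (12 up, 1 down of 17; 0.0014, and adjusted p = 0.491 with an estimated correlation). With them, cortical excitatory markers fell, 3 of 3 (median −1.77), and radial glia markers were 2 up and 7 down of 14, basal progenitor markers 4 down of 10 and neuron markers 3 up and 5 down of 12. Counts were 3664 in basal progenitors and 3073 in neurons without E12.5 replicate 2, and 1609 in basal progenitors with clustering centred within libraries. Cluster 13 held 46.2% of basal progenitors at E12.5 and cluster 12 31.2% at E15.5, and cluster 17 held 28.2% of neurons at E12.5 and cluster 18 16.7% at E15.5.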

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

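The tests of explanations in this part, and the reading of other splits of the embryos, were chosen after the results had been seen. The results that follow stood out because a test of the difference itself, between the 2 lines or between 2 classes, passed. The radial glia share differed between the lines by 20.4 percentage points (exact p = 0.005, adjusted p = 0.015; 13.4 points with another clustering seed), higher in 3 of 3 TEAD knockouts and lower in 3 of 3 YAP/TAZ knockouts than in every control of the line. The neuron share differed by −19.2 points (exact p = 0.015, adjusted p = 0.0225), but did not pass with another clustering seed (−12.9, adjusted p = 0.12). The TEAD effect in basal progenitors differed from that in radial glia for 3829 genes, and the YAP/TAZ effect for 143.

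The TEAD and YAP/TAZ effects differed for 309 genes in basal progenitors, 6 in radial glia and 1 in neurons. Of 40 drawn splits that exchanged embryos within the lines, 1 gave as many as 309, the real one, and the highest other gave 100; 1 gave as many as 6, with 4 as the highest other. The 309 argue against chance in basal progenitors but 40 draws cannot exclude it, nor the batch of YAP/TAZ knockouts. In radial glia chance stays open for the 6 genes, since the count was 0 with clustering centred within libraries or from another seed. Simulated data gave 7 false calls in this comparison, but beside planted changes, so that number cannot be set against the 6. In neurons 4 of 40 splits gave 1 gene or more, with 2 as the highest other, so the count does not exclude chance there. The gene called is Tead2, a targeted gene of the TEAD line, at 15.4 to 22.8 CPM in TEAD control neurons and 1.67 to 2.62 in TEAD knockout neurons. Its difference between the lines was −2.74 ± 0.27 (adjusted p = 0.0047; 0.0721 with doublets kept), far beyond its spread, so chance is argued against for this gene.

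Comparisons of 3 with 3 embryos have 10 splits, too few for a share under 0.05. As many genes as in the real split were called in 1 of 10 for the TEAD knockout in radial glia (1450 genes; highest other split 1), basal progenitors (989; 12) and neurons (10; 3), for the YAP/TAZ knockout in radial glia (253; 0) and basal progenitors (29; 2), and for the difference between classes in the TEAD line (3829; 0) and the YAP/TAZ line (143; 4). In YAP/TAZ knockout neurons, where no gene was called, all 10 of 10 gave as many, and the highest other gave 1. Of 80 splits exchanging classes within embryos, 1 reached 23 Hippo components and TEAD partners called between basal progenitors and radial glia (highest other 22). Between neurons and basal progenitors 1 reached 24 (highest other 22). The classes came from expression, so exchanging them lowers the counts and cannot test chance. The draws had been raised stepwise to 80 after outcomes with fewer were seen on an earlier clustering. A drawn split there reached the count of the second step. The highest other split exchanged only YAP/TAZ control replicate 3 in each case.

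Neuronal and MGE interneuron genes were lower in TEAD knockout basal progenitors (15 genes called, median log2 fold change −1.16). Radial glia cells or their RNA in this class would have to supply 69.5% of its RNA (median), where their markers allow at most 16.9%. Those markers named the classes, so misplaced cells stay open. Less free neuronal RNA in the droplets is argued against. Endothelium-like droplets held 21.5% of these genes' level in basal progenitors (median), against a fall of 55.4%, and covered the fall of 3 of 15. Another mix of clusters is argued against by medians of −0.83 or lower within each of 5 clusters. A line between the classes drawn at another point of the lineage in knockout cells cannot be told apart from a change within the class. With marker-score classes the median was −0.63, but that score holds all but 9 of the genes. For these 9 it went from −1.45 to −0.63. In radial glia the median of the 15 went from −0.52 to −1.09. A change within the class after TEAD loss stays open as a hypothesis beside a shifted line and the batches of the TEAD line, and no mechanism was tested.

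Yap1, Wwtr1 and 5 canonical YAP/TAZ-TEAD targets were higher in TEAD knockout basal progenitors (7 genes, median 0.75). Radial glia RNA would have to supply 34.2% (median), above the highest marker for 6 of 7 genes but not for Crim1 (12.3%), with the same limit. Another mix of clusters is argued against by medians of 0.59 or higher in each of 5 clusters. The line between the classes moved this pattern little, with a median of 0.68 under the marker score. The rise may thus be biological or technical, since 2 of 3 embryos per genotype were in batches of 1 genotype, and no mechanism was tested. Whether functional Tead1 was lost stays open, since its counts rose.

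The radial glia share was higher in TEAD knockouts and lower in YAP/TAZ knockouts. Radial glia per 100 basal progenitors argue against neurons lost or gained in dissociation in the TEAD line (lowest knockout 22.9 above the highest control). In the YAP/TAZ line (24.7 to 31.3, controls 36.3 to 38.7) neurons lost or gained in dissociation stay open, since radial glia shares overlapped with marker-score classes. The radial glia cluster richest in TEAD knockout cells is argued against as the whole source, because without it the TEAD difference was 9.92 points and the groups did not overlap. In the YAP/TAZ line, a batch difference cannot be told apart from genotype for the difference of −5.34 points, since every knockout is in 1 batch without a control. In the TEAD line, batch 2 held 1 embryo of each genotype (16.6% in control, 36.5% in knockout). Other batches held 1 genotype, so batch was not excluded there either. A larger pool of radial glia after TEAD loss and a smaller one after YAP/TAZ loss may each be biological or technical.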

How the results depend on the processing

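Of the tests in this part, the fits without the cluster richest in TEAD knockout cells, those with late precursors counted as basal progenitors, those with another clustering seed and every test of the difference between the lines in shares were chosen after seeing the data. Except where an alternative itself leaves out embryos, cells or counts, the cause of a change was not tested. Shares within a line or with age kept their direction in every alternative but 1, the marker score, which turned the basal progenitor difference to 2.75 points in the TEAD line and to −0.225 with age. The difference between the lines stayed past the threshold for radial glia in every alternative (13.4 to 23.4 points). For neurons it did not pass with doublets kept (−12.7), clustering centred within libraries (−17.6), another seed (−12.9) or shares of all kept cells (−15.2). For basal progenitors, where it did not pass, it turned to 7.17 with the marker score, 0.427 with clustering centred within libraries, 0.781 with run 1 only and 1.93 without the cluster richest in TEAD knockout cells, and ran from −4.09 to 0.835 without each embryo in turn. Hippo components called along the lineage stayed at 23 and at 23 to 24 for the 2 steps, and genes called with age in radial glia (5722) between 3934 and 6504.

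Counts of called genes moved by more than 1.5 times under many alternatives. With classes from the marker score, TEAD knockout counts were 872 in radial glia and 312 in neurons, the difference between the lines had 199 in basal progenitors and 55 in radial glia, and the TEAD difference between classes 1597. Clustering centred within libraries gave 865 and 17 for TEAD knockout radial glia and neurons, 0 for the lines in radial glia and 1609 with age in basal progenitors. With doublets kept, YAP/TAZ knockout basal progenitors had 19, and the lines differed for 134 in that class and 1 in radial glia. Without the cluster richest in TEAD knockout cells, YAP/TAZ knockout radial glia had 157, the lines differed for 0 genes in that class and the TEAD difference between classes was 2520. Another clustering seed gave 0 for the lines in radial glia and 13 in YAP/TAZ knockout basal progenitors, where late precursors counted as basal progenitors gave 52.

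DESeq2 called 1589 and 299 genes in TEAD knockout basal progenitors and neurons, 557, 205 and 112 in YAP/TAZ knockout radial glia, basal progenitors and neurons, and 83, 714 and 15 for the lines in the same order of classes. With no filter on low counts, TEAD knockout neurons had 56, the YAP/TAZ knockout 545, 142 and 27, the lines 70 in radial glia and 2 in neurons, and the YAP/TAZ difference between classes 729. Fits of only the 2 groups compared, which hold 6 embryos, gave 814, 316 and 1 for the TEAD knockout and 604 and 242 for YAP/TAZ knockout radial glia and basal progenitors. Batch as a term gave 646 and 2 in TEAD knockout basal progenitors and neurons. Thinned sums, which hold fewer counts, gave 769 in TEAD knockout radial glia and 1 in YAP/TAZ knockout neurons, so depth limits the first of these counts.

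The replicate number as a block (replicate block) gave 2284, 2142 and 1 for the TEAD knockout in radial glia, basal progenitors and neurons, 610 and 266 for the YAP/TAZ knockout in the first pair of classes, and 49, 1194 and 0 for the lines. Correlations of same-numbered control and knockout embryos in radial glia were 0.338, 0.195 and −0.141 in the TEAD line and −0.0398, 0.0194 and −0.06235 in the YAP/TAZ line, and not every embryo correlated best with its own number, so the numbers were not taken to pair embryos.

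Without each embryo in turn, the TEAD knockout counts ran from 693 to 4164 in radial glia, 372 to 3979 in basal progenitors and 1 to 2524 in neurons, each highest without control replicate 1. YAP/TAZ knockout counts ran from 68 to 610, 5 to 284 and 0 to 10. The lines differed for 1 to 1814 genes in radial glia, 139 to 2401 in basal progenitors and 1 to 727 in neurons, and the YAP/TAZ difference between classes was 24 to 613. With age, counts were 3664 to 5376 in basal progenitors and 3073 to 4893 in neurons.

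An estimated correlation left 4 of 80 gene list calls; fry called 64, of which 42 were among the 80 in the same direction. Over genes with a mean log2 CPM of at least 4, Pearson correlations of the 2 effects were 0.459 in radial glia, 0.112 in basal progenitors and 0.400 in neurons, against 0.501, 0.204 and 0.309, and Spearman correlations 0.220, −0.0273 and 0.254, against 0.355, 0.109 and 0.279.

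Of results of single genes named in the text 169 were called, of which 109 kept their call and direction in every alternative and 57 lost the call in at least 1 while keeping their direction. Among 3870 values under alternatives, 271 lost a call, 15 gained one and 17 changed direction. Directions turned for 8 gene results. In TEAD knockout radial glia, the marker score gave Slc32a1 −0.27, Dlx6 −0.24, Sp9 −0.39 and Prox1 −0.47, and batch as a term gave Ubr7 −0.067. With age in radial glia, Yap1 had 0.066 with clustering centred within libraries, 0.043 with another seed and 0.15 with thinned sums, and ran from −0.083 to 0.011 without E15.5 replicates 1 and 2. In the YAP/TAZ difference between classes, Yap1 had 0.0098 with another seed and ran from −0.158 to 0.055 without control replicate 3 and knockout replicate 1. Wwtr1 there had 0.0199 with the marker score, 0.218 with another seed and 0.026 without the cluster richest in TEAD knockout cells, ran from −0.276 to 0.091 without knockout replicates 1 and 2, and had 0.022 without control replicate 3 and 0.023 without knockout replicate 3.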

Other observations

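Some genes outside the naming rule moved in both knockouts; they were chosen after their values were seen, from a longer list of genes, partly because their calls held under most alternatives. Axin2, a feedback inhibitor of Wnt signalling, was 8.45, 14.1 and 9.5 CPM in TEAD controls and 20.4, 25.8 and 28.3 in TEAD knockouts, in radial glia (log2 fold change 1.22 ± 0.24, adjusted p = 0.0071), and rose by 1.69 ± 0.25 with YAP/TAZ loss (0.0044). Its call in the TEAD line was lost without the cluster richest in TEAD knockout cells (0.84, adjusted p = 0.0997). Lef1, a transcription factor of the same pathway, rose in radial glia by 2.75 ± 0.52 and 3.48 ± 0.54 (adjusted p = 0.0056 and 0.0051), and in basal progenitors by 2.80 ± 0.32 and 3.06 ± 0.32 (0.00022 and 0.001). Each was higher in 3 of 3 knockouts than in every control of its line.

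Id3, an inhibitor of bHLH factors, rose in radial glia from 22.8, 31.7 and 27.0 CPM to 70.5, 99.8 and 92.3 in the TEAD line (1.69 ± 0.20, adjusted p = 0.00031) and by 1.975 ± 0.20 in the YAP/TAZ line (0.00028). Foxj1, a master regulator of motile cilia, fell from 6.84, 10.0 and 6.52 CPM to 1.04, 1.61 and 1.69 in the TEAD line (−2.49 ± 0.27, 0.00023) and had −2.22 ± 0.33 in the YAP/TAZ line (0.0043). No test of these genes as a set was run, and no explanation is offered for them.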
